A study of Chlamydomonas reinhardtii with 12 samples.

How the data were processed

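Illumina RNA sequencing was used to measure transcript levels in cultures of the unicellular green alga Chlamydomonas reinhardtii. The 12 samples were 4 strains at 3 stages, with 1 sample per strain and stage. The strains were the wild type CC-124, the mutant crr1, the mutant rescued with CRR1 (crr1:CRR1) and the mutant rescued with the form named crr1dCys. The stages were light-oxic culture and dark-anoxic incubation for 0.5 h or 6 h. Per the labels' protocols, aliquots of a light-grown culture were sealed in bottles and stirred in a dark room, and reference aliquots went back to the growth conditions. Light and oxygen were therefore withdrawn together, and their contributions cannot be separated in this design.

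The authors deposited 1 table of 17301 gene models with normalised values in 20 columns. Bowtie is the tool named per the submitters' processing notes, with no version. The genome build, the annotation, the counting method, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so values of near-identical or overlapping models are uncertain. No header names the unit. The values deposited by the authors were read as RPKM (reads scaled to model length in kilobases and to the depth of the library) from the values themselves. Low values of a model fell on steps whose size gave a whole number of bases for the model length. At the inferred depths, 99.6% of 1220 low models had a whole length within 0.1 base, against a mean of 20.4% at 21 other trial depths. The depth taken was the largest that did so, and it gave 12001000 to 18894000 reads per column. In a model of 1 kilobase, 1 RPKM then rests on 12 reads or more. A smaller depth, at which every length is multiplied by the same whole number, would fit the steps as well, so these depths are upper bounds as far as the steps go. Values per column summed to between 736062 and 957719, between 959 and 1347 models were listed at 0, and 6.21% of all values were 0.

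Column names are abbreviations of the strains with a time and a series number (TS1, TS2 or TS4). They were matched to the labels by name alone. The abbreviations of CC-124 and crr1dCys are unambiguous, the abbreviation with a capital C in second place was read as crr1:CRR1, and the remaining one as crr1. The reading of the last 2 is by elimination. 8 samples had 2 columns and 4 had 1 column. For tests, fold changes and responses, repeat columns of a sample were averaged on the log2 scale. The RPKM levels printed beside them are arithmetic means of the columns, so where repeat columns lie far apart a level and a log2 response do not convert into each other. In both cases a sample counted as 1 replicate, because nothing in the labels says that they came from separate cultures. CC-124 occurs in TS2 only, TS4 holds crr1:CRR1 only, and crr1 at 0.5 h occurs in TS1 only. No column was left without a sample.

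Values were analysed as log2(RPKM + 1), so a fold change understates the change of models with low values. Models with a mean of at least 1 RPKM over the 12 libraries were tested, which left 14311. Tests were made with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the models tested. Each time comparison used all 12 libraries with strain as a block, leaving 6 residual degrees of freedom. The 4 strains thus served as the replicates of a stage, and p-values measure the spread of responses between strains, not between cultures of a strain. That spread was pooled over all stages, so a p-value at 0.5 h also depends on the 6 h libraries. A model was called when its adjusted p was below 0.05 and its log2 fold change at least 1 in size. Differences of the response of crr1 or crr1dCys from the mean response of both strains with full-length CRR1 (CC-124 and crr1:CRR1) were tested as interactions at an adjusted p of 0.05. That fit had 2 residual degrees of freedom and assumes that the lone strain varies like the other pair. Beside it stands a rule of size without a test. It counts models for which both full-length strains lay at least 2 log2 units to the same side of crr1, with log2(RPKM + 1) of at least 2 in a library. The same count was made for each of the 12 ways of setting 1 strain against a pair. Strain differences in light-oxic culture were counted by the same size, with no test. Correlations of responses are across genes, which are not independent replicates.

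The scripts were tested on simulated data with 14311 models, 50 of them changed at each size. For 6 h against light-oxic, 86%, 96%, 100% and 100% of models changed by 1, 2, 3 and 4 log2 units were recovered, with 10 false calls. For the crr1 difference at 6 h, 0%, 0%, 12% and 52% were recovered, with 3 false calls. In the simulation, an interaction of under 4 log2 units was therefore mostly out of reach, and real data can be harder.

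The table pairs no gene names with its identifiers. Of the 17301 models, 12666 matched a locus tag of the reference table for assembly Chlamydomonas_reinhardtii_v5.5, and none of the 17742 loci there carries a symbol other than its tag. That table was used only to find which genes neighbour each other and how far apart they lie, and no coordinates are given. The 24 gene lists fixed before the data were examined are lists of symbols and matched 0 members, so list tests and the level of CRR1 itself are not analysed here. The rule for named genes, also fixed before the data were examined, took up to 10 genes with a symbol each way. For the 0.5 h and 6 h responses it required an adjusted p below 0.05, the same direction in all 4 strains and log2(RPKM + 1) of at least 2 in a stage mean, ranked by log2 fold change. For the crr1 difference it ranked the models that met the rule of size. Since no symbols were at hand, the rule was applied without that requirement and limited to 2 models each way, given by identifier.

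Alternatives covered the pseudocount, the low-value filter, the scaling, the strain block, the threshold, the size in the rule of size and the omission of each strain. Others were chosen after seeing the data. They were the omission of the TS4 column of crr1:CRR1 at 6 h, the log2 of the mean RPKM over repeat columns, and the columns of TS1 or TS2 alone. Figures and neighbour statistics were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.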

Results

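The data describe how transcript levels of Chlamydomonas reinhardtii changed when light-grown, aerated cultures were moved to dark, sealed bottles, and whether the change differed without a functional CRR1. CRR1 is a transcription factor known as the copper response regulator of this alga, and crr1dCys is known as a form of it without the cysteine-rich end of the protein. 4 strains were each measured at 3 stages, which gave 12 samples in 20 columns of RPKM values. The columns rested on 12001000 to 18894000 reads, as inferred from the steps of the low values. There was no replicate culture of a strain at a stage in the labels, so time responses were judged against the spread over 4 strains. These are not fully independent replicates, because crr1, crr1:CRR1 and crr1dCys are a mutant and its rescued strains. Across genes, their 0.5 h responses had r of 0.858 to 0.922 with each other and 0.659 to 0.742 with CC-124.

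Repeat columns were close to each other in 7 of the 8 samples that had a pair. Pearson's r across genes of log2(RPKM + 1) lay between 0.985 and 0.992, and between 6 and 31 of 14297 models differed by 2 log2 units or more. In the remaining sample, crr1:CRR1 at 6 h, the TS1 and TS4 columns had r = 0.879 and 901 models differed by that much. The SD of the difference was 1.09 log2 units there, against 0.257 to 0.364 in the other pairs. The first 2 principal components took 29.7% and 22.4% of the variance over the 20 columns.

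**Figure D1:**
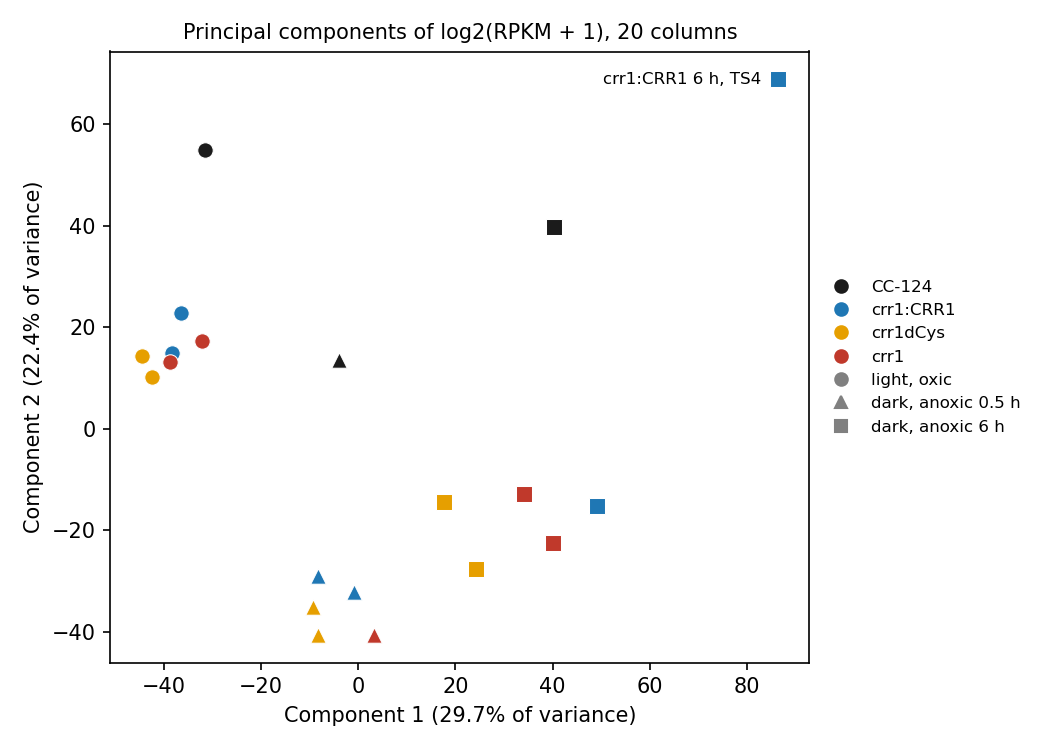
Scores of the 20 columns on the first 2 principal components of log2(RPKM + 1), with the share of variance of each in percent on the axes. Each point is a column, colours mark the 4 strains and shapes the 3 stages. The TS4 column of crr1:CRR1 at 6 h lies away from the other 6 h columns, and the CC-124 columns lie apart from the other strains at each stage.

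The first comparison asked which transcripts had changed after 0.5 h in the dark without oxygen. 488 gene models rose and 704 fell against light-oxic culture, which is 3.41% and 4.92% of the 14311 tested. Of these, 486 and 696 moved the same way in all 4 strains, as did 61.0% of all models tested. The strains were the replicates of the test, so such agreement among called models is largely built in. Cre09.g391650.t1.1 rose the most, from 4.75 ± 2.60 to 127 ± 63.9 RPKM (mean ± SD over strains, n = 4), a log2 fold change of 4.46 (SE 0.35, limma adjusted p = 2.06e-05). Without the TS4 column of crr1:CRR1 at 6 h, its limma adjusted p at 0.5 h was 4.27e-07 with the same fold change. Cre13.g603550.t1.1 rose from 8.21 ± 2.73 to 145 ± 84.0 RPKM (n = 4), by 3.89 log2 units (SE 0.41, limma adjusted p = 9.93e-05). In CC-124 it reached 270 RPKM, above the 96.8 to 109 RPKM of the other strains. Cre04.g215050.t1.1 fell from 21.8 ± 3.42 to 0.691 ± 0.348 RPKM (n = 4), with a log2 fold change of -3.78 (SE 0.47, limma adjusted p = 0.000232). Cre06.g309000.t1.1 fell from 89.8 ± 90.2 to 2.07 ± 1.95 RPKM (n = 4), with a log2 fold change of -3.75 (SE 0.77, limma adjusted p = 0.00398). Its light-oxic level ranged from 0.988 RPKM in CC-124 to 207 RPKM in crr1dCys. Its response was -0.89 log2 units in CC-124 and between -4.16 and -5.39 in the other strains. With the TS2 columns alone, its log2 fold change was -3.49 and the limma adjusted p was 0.0897. Within the series, TS1 columns alone gave 502 rising and 791 falling models, and TS2 columns alone gave 530 and 547. TS1 holds no CC-124, and TS2 holds no crr1:CRR1 and no crr1 at 0.5 h. Counts by series therefore differ in strains as well as in series. With a pseudocount of 0.1 the number of rising models was 747, and with a pseudocount of 5 the counts were 248 and 299.

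After 6 h, 643 models rose and 1006 fell against light-oxic culture (4.49% and 7.03%). Of them, 621 and 985 moved the same way in all 4 strains, which is again largely built into the test. Among all models tested the share was 53.6%. Cre16.g661200.t1.1 was listed at 0 in light-oxic culture in 3 of the 4 strains and at 0.0265 RPKM in crr1:CRR1. At 6 h it stood at 49.9 ± 26.9 RPKM (n = 4), a rise of 5.36 log2 units (SE 0.39, limma adjusted p = 1.63e-05). Cre06.g275350.t1.2 rose from 0.915 ± 0.365 to 67.1 ± 23.4 RPKM (n = 4), by 5.09 log2 units (SE 0.33, limma adjusted p = 9.62e-06). Both models had intermediate means at 0.5 h, of 0.620 ± 0.404 and 4.82 ± 2.70 RPKM (n = 4). Cre12.g546600.t1.2 fell from 135 ± 119 to 1.64 ± 1.28 RPKM (n = 4), with a log2 fold change of -5.34 (SE 0.50, limma adjusted p = 5.83e-05). The fall was -2.82 log2 units in CC-124 and between -5.83 and -6.50 in the other strains. Cre06.g309000.t1.1 continued to 0.213 ± 0.258 RPKM (n = 4), with a log2 fold change of -4.83 (SE 0.77, limma adjusted p = 0.000806). Its fall was -0.99 log2 units in CC-124, from 0.988 RPKM in the light, and between -4.87 and -7.05 in the other strains. TS1 columns alone, without CC-124, gave 671 rising and 1200 falling models, and TS2 columns alone, without crr1:CRR1, gave 689 and 846. With a pseudocount of 5 the counts were 287 and 506. The surplus of falling models depended on the scaling, with 699 rising and 923 falling under median of ratios scaling and 738 and 829 under quantile normalization.

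Between 0.5 h and 6 h in the dark, 487 models rose and 743 fell. TS1 columns alone gave 446 and 752, and TS2 columns alone 403 and 561, again from different sets of strains. Set together, the 3 comparisons describe the course of the response. Of the 488 early risers, 220 were also called higher at 6 h, and 146 were called lower at 6 h than at 0.5 h. Cre09.g391650.t1.1 stood at 38.7 ± 23.1 RPKM (n = 4) at 6 h, below its 0.5 h mean. Cre13.g603550.t1.1 stood at 189 ± 122 RPKM (n = 4), lower than at 0.5 h in CC-124 (226 RPKM), crr1dCys (86.1 RPKM) and crr1 (97.2 RPKM). Its crr1:CRR1 value of 346 RPKM joins 158 RPKM in TS1 and 533 RPKM in the TS4 column that stood apart. Of the 704 early fallers, 244 were also called lower at 6 h, and 163 were called higher at 6 h than at 0.5 h. Cre04.g215050.t1.1 stood at 12.9 ± 15 RPKM (n = 4) at 6 h, with 34.9 RPKM in CC-124, 10.1 RPKM in crr1dCys and 3.39 RPKM in crr1. In crr1:CRR1 it had 5.98 RPKM in TS1 and 0.344 RPKM in TS4. A further 178 models were late risers, called higher at 6 h than at both other stages and not called higher at 0.5 h, and 388 were late fallers by the same definition. Calls both ways against light-oxic culture were rare, with 9 models that rose at 0.5 h and fell at 6 h, and 1 that did the opposite. The 0.5 h libraries enter both steps of such a course, so a chance deviation at 0.5 h can make a model appear to rise and then fall. With a pseudocount of 0.1, 739 models rose and 1133 fell between 0.5 h and 6 h, and with 5 the counts were 188 and 365.

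The 0.5 h and 6 h responses shared their light-oxic libraries. Their log2 fold changes had r = 0.572 across genes, against 0.497 in simulated unchanged groups with the same controls. The covariance was 0.235, against 0.0165 simulated, a difference of 0.219. With the controls split by strain into separate pairs, r lay between 0.443 and 0.544 over 6 splits. Independent lists would share 21.9 rising and 49.5 falling models, where 220 and 244 were shared. Simulated unchanged groups with the same controls shared 0.01 rising and 0.01 falling models on average over 100 simulations. The first value leaves out the shared controls and the second leaves out the effects.

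The question behind the strains was which part of the response needs CRR1. The largest difference by the rule of size belonged to Cre17.g700950.t1.1. At 6 h it reached 10497 RPKM in CC-124 and 836 RPKM in crr1:CRR1, 23.9 RPKM in crr1dCys and 0.0642 RPKM in crr1. In light-oxic culture the 4 strains had 31.9, 1.59, 1.22 and 0.381 RPKM in that order. Its response was 8.01 log2 units (SE 0.82) higher in the full-length strains than in crr1. The interaction test over all columns gave it a limma adjusted p of 1. The crr1:CRR1 value at 6 h joins 1609 RPKM in TS1 and 62.4 RPKM in TS4, and the crr1dCys value joins 40.7 RPKM in TS1 and 7.03 RPKM in TS2. Without that TS4 column the difference was 9.17 log2 units, with a limma adjusted p of 0.00659.

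Cre16.g651050.t1.1 was at 107 RPKM in CC-124 and 11.0 RPKM in crr1:CRR1 at 6 h, from 0.206 and 0.124 RPKM in the light, and was listed at 0 in crr1. In crr1dCys its columns disagreed in level and direction, with 86.9 RPKM in the light and 38.7 RPKM at 6 h in TS1, and 2.94 and 6.39 RPKM in TS2. Its crr1:CRR1 columns at 6 h had 21.6 RPKM in TS1 and 0.538 RPKM in TS4. In the other direction, Cre08.g368850.t1.1 went from 0.827 to 137 RPKM in crr1 and from 0.362 to 71.4 RPKM in crr1dCys, but from 0.739 to 17.6 RPKM in crr1:CRR1, which joins 31.0 RPKM in TS1 and 4.16 RPKM in TS4. In CC-124 it was high throughout, at 761 RPKM in the light and 632 RPKM at 6 h. In TS1 alone, it rose from 0.465 to 31.0 RPKM in crr1:CRR1. Its light level in crr1:CRR1 was as low as in crr1, so the flat response of CC-124 cannot be ascribed to CRR1 alone. Cre01.g045200.t1.1 went from 36.4 to 276 RPKM in crr1 and from 44.6 to 253 RPKM in crr1dCys, and from 29.5 to 32.1 RPKM in CC-124. Its crr1:CRR1 columns at 6 h had 225 RPKM in TS1 and 3.23 RPKM in TS4, so its place among these models rests on TS4. Differences of response from crr1 were 4.55 (SE 1.79), -4.92 (SE 1.26) and -3.36 (SE 0.65) log2 units for these 3 models, each with a limma adjusted p of 1. For Cre01.g045200.t1.1 the difference was -1.92 log2 units without the TS4 column and -2.42 with the log2 of the mean RPKM.

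**Figure D2:**
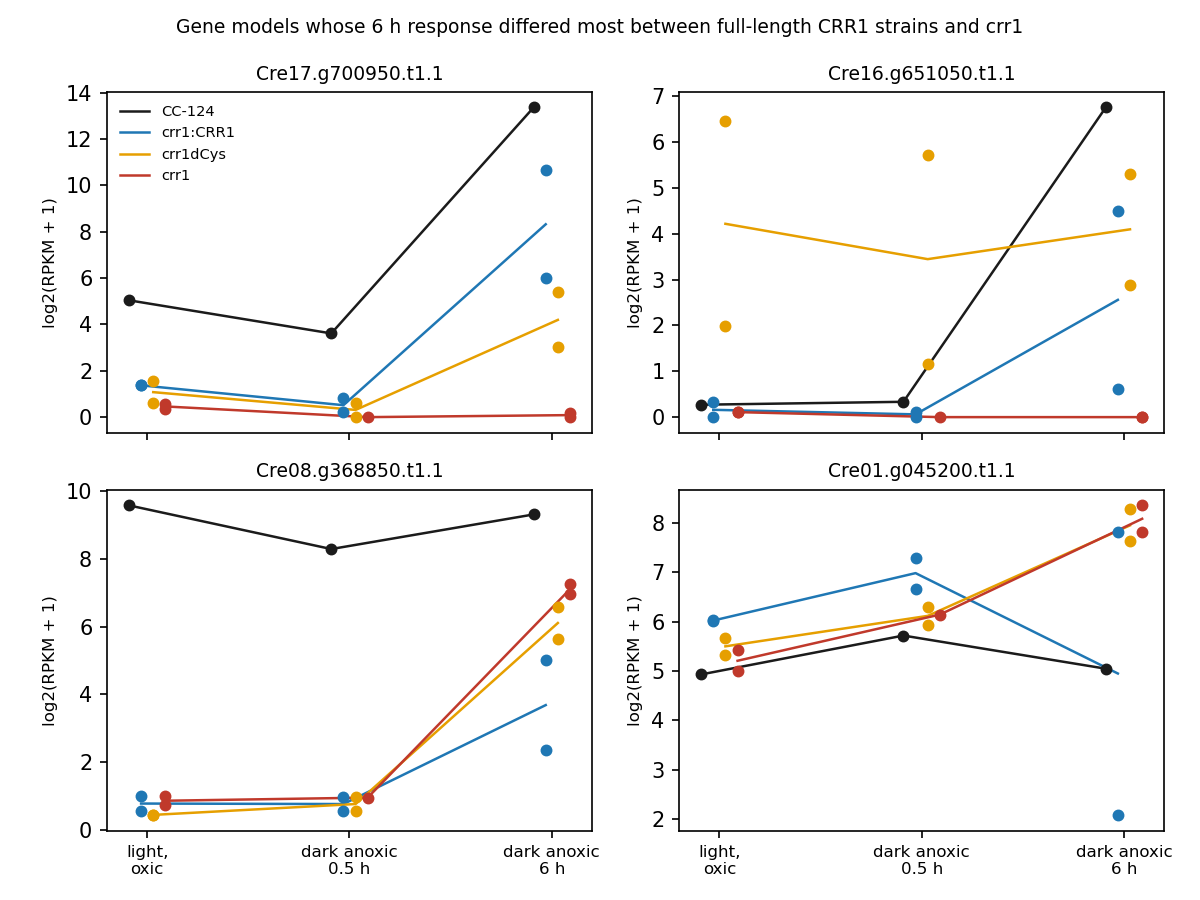
Levels of 4 gene models as log2(RPKM + 1) at the 3 stages, with a point for each column and a line through the mean of the columns of each strain. Cre17.g700950.t1.1 at 6 h stands at 10497 RPKM in CC-124 and 0.0642 RPKM in crr1, and the 2 crr1:CRR1 columns at 6 h lie far apart in each panel.

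Over all models, the interaction test with limma called 0 for crr1 and 0 for crr1dCys at either time. At an unadjusted p under 0.05 there were 460 models for crr1 at 6 h (3.21%), 218 for crr1 at 0.5 h (1.52%), 878 for crr1dCys at 6 h (6.14%) and 70 for crr1dCys at 0.5 h (0.489%). If nothing differed and the lone strain varied like the full-length pair, a share of about 0.05 would pass by chance. The residual spread came only from the difference between the responses of CC-124 and crr1:CRR1. Their 0.5 h responses had r = 0.742 across genes, against 0.896 between crr1:CRR1 and crr1. The spread also includes the TS4 column of crr1:CRR1 at 6 h. The shares therefore cannot be read against 0.05, and that includes the higher share of crr1dCys at 6 h. Without the TS4 column of crr1:CRR1 at 6 h, 2 models were called for crr1 at 6 h and 0 in the other 3 comparisons. The counts at an unadjusted p under 0.05 were then 363 for crr1 at 6 h, 380 for crr1 at 0.5 h, 852 for crr1dCys at 6 h and 105 for crr1dCys at 0.5 h. In simulated data this test recovered 52% of differences of 4 log2 units and 0% of those of 2 units. In the real data, the difference of 8.01 log2 units (SE 0.82) of Cre17.g700950.t1.1 was not called over all columns. A count of 0 thus leaves room for large differences as well as moderate ones.

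By size alone, 15 models responded more strongly upward at 6 h in both full-length strains than in crr1, and 10 lay the other way. Without the TS4 column the counts were 40 and 3, and 9 and 2 models were shared between the settings. With a pseudocount of 0.1 the counts were 27 and 40, with a pseudocount of 5 they were 4 and 4, and with a size of 1 log2 unit they were 79 and 185, so which side was larger depended on the setting. Among the 12 ways of setting 1 strain against a pair, the crr1 total of 25 had rank 8 with all columns. With the other pairs, crr1 as the single strain gave 6 and 14. CC-124 as the single strain gave 77 to 113, crr1:CRR1 gave 68 to 111 and crr1dCys gave 8 to 44. Without TS4 the crr1 total of 43 had rank 4, below CC-124 at 58 to 114 and above crr1:CRR1 at 4 to 22 and crr1dCys at 8 to 40. With the other pairs, crr1 gave 15 and 14 there, within the ranges of crr1:CRR1 and crr1dCys. With 1 strain in place of both full-length ones, crr1:CRR1 against crr1 within TS1 gave 54 higher and 9 lower models, with 11 of the 15 and 1 of the 10 among them. CC-124 against crr1 within TS2 gave 118 higher and 78 lower, with 14 of the 15 and 10 of the 10. CC-124 has TS2 columns only, so its values here are those that selected the 15 and the 10. The TS1 columns also took part in that selection. These overlaps are therefore no independent check of the models. At 0.5 h, 3 models were higher and 5 lower in the full-length strains than in crr1. This total of 8 had rank 4 of 12, below CC-124 as the single strain at 70 to 81 and above crr1:CRR1 at 2 to 3 and crr1dCys at 0 to 2.

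**Figure D3:**
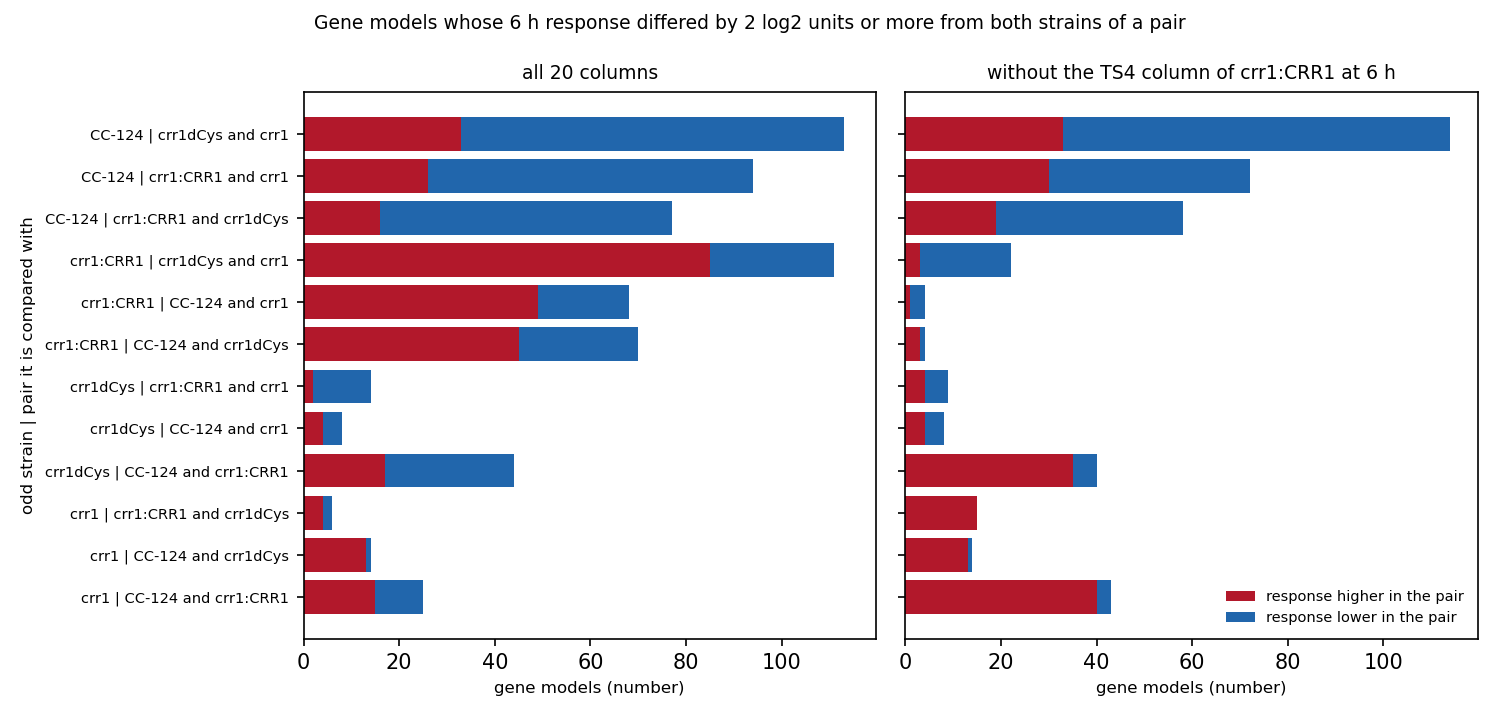
Number of gene models whose 6 h response differed by 2 log2 units or more from both strains of a pair, for the 12 choices of a single strain and a pair. Bar parts show responses higher or lower in the pair, on the left with all 20 columns and on the right without the TS4 column of crr1:CRR1 at 6 h. Bars with CC-124 as the single strain reach 113 and 114 models, against 25 and 43 for crr1 set against both full-length strains, and crr1:CRR1 as the single strain goes from 68 to 111 models on the left to between 4 and 22 on the right.

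For the models that met the rule, crr1dCys stood nearer to crr1 than to the full-length strains in 11 of 15 and in 9 of 10. For the 15, the median 6 h response was 2.68 log2 units in the full-length strains, 0.08 in crr1dCys and -0.37 in crr1. Without the TS4 column, crr1dCys was nearer to crr1 in 24 of 40, with medians of 3.08, 1.25 and -0.12. Among all 14311 models it was nearer to crr1 in 9795, or in 8708 without that column, and no test was made of the difference between these shares.

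Whole responses were also compared between strains, across genes. At 0.5 h the highest correlation was between crr1:CRR1 and crr1dCys, with r = 0.922, and crr1:CRR1 and crr1 had r = 0.896. CC-124 had r between 0.659 and 0.742 with the other 3. At 6 h crr1dCys and crr1 had r = 0.867, and crr1:CRR1 and crr1 had r = 0.747, or 0.896 without the TS4 column. CC-124 had r between 0.628 and 0.672 with the others, and 0.762 with crr1:CRR1 without that column.

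Strains already differed in light-oxic culture. CC-124 differed by 2 log2 units or more from crr1:CRR1 in 227 models, from crr1 in 258 and from crr1dCys in 304. The mutant and its rescued strains were closer, with 7 models between crr1:CRR1 and crr1, 30 between crr1dCys and crr1 and 35 between crr1:CRR1 and crr1dCys. These counts carry no test. CC-124 was measured in TS2 only, while the TS1 and TS2 columns of crr1 and crr1dCys in the light differed from each other in 6 and 25 models.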

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

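Of 51 sets of 4 strain values, 9 had a strain whose gap to the nearest other was large against the whole range. For normal values chance gives about 1 in 20 sets, but most sets hold RPKM levels, which need not be normal. That rate also does not apply to 7 of the 9, which are in 3 models picked for a difference between strains. Values of a gene at several stages are not independent either. No explanation of these values was tested. CC-124 was the strain apart in 6 of the 9. Cre17.g700950.t1.1 was at 31.9 RPKM in the light, 11.2 RPKM at 0.5 h and 10497 RPKM at 6 h in CC-124, above the other strains each time. Cre08.g368850.t1.1 was at 761 RPKM in the light and 311 RPKM at 0.5 h in CC-124, against under 1 RPKM elsewhere. Cre13.g603550.t1.1 was at 270 RPKM at 0.5 h in CC-124. In crr1dCys, Cre16.g651050.t1.1 was at 44.9 RPKM in the light and 26.5 RPKM at 0.5 h, above the other strains. These means rest on TS1, with 86.9 and 51.8 RPKM, while TS2 had 2.94 and 1.25 RPKM. Cre16.g661200.t1.1 had 0.0265 RPKM in the light in crr1:CRR1 and was listed at 0 in the others, so its gap equals the whole range by construction.

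At 6 h, Cre17.g700950.t1.1 and Cre16.g651050.t1.1 had responses above 0 in both full-length strains and below 0 in crr1, at -0.37 and -0.11 log2 units. The opposite signs themselves were not tested, and the interaction test over all columns gave limma adjusted p = 1 for both. In crr1 these models were already at 0.381 and 0.0787 RPKM in the light, so a fall there is near the floor of the measurement.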

How the results depend on the processing

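Settings chosen after seeing the data were the omission of the TS4 column, the log2 of the mean RPKM and the single series. No named gene changed sign. The time counts stayed within 1.5 times under no filter, both other scalings, no strain block, each strain left out, each series alone and the settings for repeat columns. For each value below that moved, the cause was not tested unless stated. With a pseudocount of 0.1, 747 models rose at 0.5 h, 739 rose and 1133 fell from 0.5 h to 6 h, and 27 and 40 met the rule of size for crr1. With a pseudocount of 5 the counts were 248 and 299 at 0.5 h, 287 and 506 at 6 h, 188 and 365 between them, and 4 and 4 by the rule of size. A larger pseudocount shrinks each fold change by construction. By adjusted p alone, without a fold threshold, 2560 rose and 2844 fell at 0.5 h, 2834 and 3590 at 6 h, and 2406 and 2875 between them.

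The count by size for crr1 at 6 h (15 higher and 10 lower) moved most, and the larger side turned at a pseudocount of 0.1, without CC-124 (42 and 129) and at 1 log2 unit. Leaving out CC-124 or crr1:CRR1 gave 42 to 121 higher and 64 to 129 lower models, where only 1 full-length strain had to differ. At 1 log2 unit there were 79 and 185, and at 3 units 2 and 1. The log2 of the mean RPKM gave 24 and 4, and the omission of the TS4 column 40 and 3. Interaction calls for crr1 at 6 h were 1 with the log2 of the mean RPKM and 2 without TS4. They were 0 with either pseudocount, no filter, both other scalings and no strain block. No interaction value was given with crr1dCys left out or for a single series. Both settings called Cre17.g700950.t1.1, whose limma adjusted p ranged from 0.00659 to 1 over its alternatives (0.0213 with the log2 of the mean). The other call without TS4 was Cre07.g346900.t1.2, named after its value was seen, at 4.32 log2 units (limma adjusted p = 0.0333). Cre06.g309000.t1.1 at 0.5 h was no longer called in TS2 alone (log2 fold change -3.49, limma adjusted p = 0.0897). That fit has fewer libraries, but TS1 alone, also with fewer, gave a limma adjusted p of 4.68e-05. TS2 holds CC-124 and TS1 does not. The 0.5 h response of this model was -0.89 log2 units in CC-124, against -4.16 to -5.39 in the other strains. The cause was not tested.

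A count test was not run because the table holds RPKM, and list tests were not run because no list matched. Interaction tests without a full-length strain were given no value, since no residual degrees of freedom would remain. Depth limits low models: 1 RPKM in a model of 1 kilobase is 12 reads in the shallowest column at the inferred depth, and fewer if the true depth is smaller.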

Other observations

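The tests of depth, of leading genes and of a swapped label were chosen after the column in question had been seen to stand apart. That column is TS4 of crr1:CRR1 at 6 h, in which 172 of 14311 models were at least 2 log2 units above the TS1 column of the same sample and 726 at least 2 units below. A lower number of reads and a few leading genes are argued against by its 15315000 reads, above the lowest of the other 19 columns at 12001000, and by the 12.5% of RPKM in its 10 leading genes, under the highest share elsewhere of 15.8%. It had the most models at 0 of the 20 columns, 1347 against at most 1203 elsewhere, so a library of lower complexity at that number of reads stays open. More of the same 6 h response is argued against by its difference from TS1, with r = -0.14 across genes with the mean response of the other 3 strains. On component 1, which parted light-oxic from 6 h columns, it did lie furthest, at 86.3 against 49.2 for that TS1 column. The column itself helped to shape that component, and it also had the highest score on component 2, at 68.8. A swap with another column of the table is argued against by its highest correlation with a column of another sample, r = 0.883, where each of the other 19 columns reached at least 0.936 with its nearest column. A sample from outside the table under this name, a different culture state in TS4 and a fault in the preparation stay open and were not tested.

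For each time comparison, the 8 libraries were regrouped in the 35 ways that give 4 and 4. Only 1 of 35 splits, the real one, gave as many models. The real counts were 1192 at 0.5 h, 1649 at 6 h and 1230 between the dark stages, and the highest count of any other split was 0 in each case. Every other split mixes the stages, so the stage effect enters its spread and lowers its count. The 35 splits therefore cannot exclude chance for these totals. The libraries are also paired by strain, and 8 of the splits part all 4 strains. Among these 8 the highest count other than the real one was also 0, but 8 are too few for a share under 0.05.

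Neighbouring genes changed together more often than shuffled genes. Among 8509 pairs of adjacent tested genes in the reference table (assembly Chlamydomonas_reinhardtii_v5.5), 33 pairs both rose at 6 h and 86 both fell, against means of 14.8 and 46 and highest values of 31 and 64 over 1000 shuffles within chromosomes. Pairs of a riser beside a faller numbered 32, against a mean of 52.2. The correlation over pairs was small, with r = 0.0958 for the 6 h response and 0.117 for 0.5 h, and highest shuffled values of 0.0327 and 0.0376.

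A technical candidate explanation is reads shared between abutting models, but r over the 1012 pairs at least 1000 bases apart was 0.0203 within a shuffled range that reached 0.0999, so even the correlation of all pairs would have passed unseen. Of these far pairs, 4 both rose and 13 both fell, against means of 1.76 and 5.45 and highest values of 8 and 13 over the shuffles. Another candidate explanation is regional variation between libraries unrelated to the stage. Differences between repeat columns gave r up to 0.0794 over the same pairs, below the 6 h value but above the bound of 0.5 times that value set for excluding this. Neither can be told apart from a shared response of neighbouring genes, because far pairs are few and the repeat columns show part of the effect.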
